A study of Mus musculus with 24 samples.

How the data were processed

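Polyadenylated RNA of brain endothelial fractions was sequenced as stranded libraries on an Ion Proton instrument, in 24 libraries, 3 for each of 2 genotypes at 4 stages, grouped as the labels name them. The deposited tables give, for each of 45468 genes on genome build mm10, raw counts of reads on 1 strand, which the authors did not scale. The authors' FPKM column divides the counts by the gene length and the library total, and the authors' TPM column is length-scaled to a common sum. Their notes name Trim Galore 0.4.1, FastQC, STAR 2.5.3a and SAMtools 1.5, without saying what each did. The annotation release and the floxed exons are not stated. The counts were analysed, and the FPKM and TPM columns were checked against them and not used further. Gene symbols came with the tables. Of their gene identifiers, 44948 were found in a reference annotation of the same build, where 87.3% had the same start after adding 1 and 87% the same end.

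The floor taken for a count of 0, 3 counts, corresponds to 0.151 to 0.244 CPM. The most abundant gene took 0.64% to 1.22% of a library. Replicates spread beyond counting error, with a chi-square per degree of freedom of 4.83 to 56.4 by group.

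Genes with a mean of at least 10 counts in at least 1 of the 8 groups were tested, 17159 in all. Counts were scaled by TMM (factors 0.861 to 1.14), and CPM values and log2 fold changes use those library sizes, the latter with a prior count of 2. The edgeR 4.0.16 quasi-likelihood test was fitted to all libraries with 1 mean per group and 16 residual degrees of freedom, in R 4.3.3. The contrasts were KO against wt at each stage and averaged over stages, their differences between stages (the interaction, by an F test and by pairs of stages), and wt against wt between stages. Tests were two-sided and adjusted by Benjamini and Hochberg, and "called" or "passed" means an adjusted p under 0.05. Genes with 3 or fewer counts in a group are given as a ratio of counts with its 95% interval, or as a lower bound against the floor of 3 counts over the group. The pipeline was tested on counts simulated for P9, but real spread may differ. It recovered 38.8%, 77.6% and 95.5% of 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. False calls were 3 of 16959 unchanged genes and 3 for the interaction.

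The 20 gene lists covered Wnt targets, Wnt receptors and effectors, junctions, barrier transporters, caveolae and vesicle genes, endothelial identity, SoxF, Notch, arterial, venous, tip cell and angiogenic, cell cycle, matrix, TGF-beta and BMP, flow-responsive, inflammatory, interferon, hypoxia and glycolysis, endothelial-to-mesenchymal, and dissociation and stress genes. Another 13 lists held markers of pericytes, smooth muscle, fibroblasts, astrocytes, neurons, neural progenitors, oligodendrocyte precursors, oligodendrocytes, microglia and macrophages, other leukocytes, red cells, ependyma and choroid plexus, and peripheral and lymphatic endothelium. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, which compares a list with the remaining genes. P values were adjusted over the lists and contrasts of each family, 100 for KO contrasts and 80 for wt contrasts, with markers adjusted apart. Calls within a list were also counted adjusted over the list alone.

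Named genes followed a rule. Sox17 came first. Each contrast gave up to 10 rises and 10 falls with the largest fold change among called genes whose libraries did not overlap between groups, with a higher group mean of at least 50 counts and a symbol not of the Gm-number, Rik, AC, AL or BC-number or pseudogene (-ps) kind. Each list gave up to 4 called members with the smallest adjusted p per contrast. Sox17, Sox7, Sox18, Lef1, Axin2, Cldn5, Plvap, Slc2a1, Mfsd2a, Cdh5 and Pecam1 were always named. Genes outside it are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

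Alternatives were DESeq2 1.42.0 size factors, the DESeq2 test, robust limma-trend, no low-count filter, a fold threshold of log2 1, fits of the 6 compared libraries alone, a replicate block, leaving out each library, an estimated correlation for lists, and, for the maturation correlation, a mean of at least 100 counts. Scaling to endothelial identity genes and leaving out both E15.5 libraries numbered 3 were chosen after seeing the data. KO and wt libraries were regrouped in all 10 splits of 6 libraries, and in 100 random regroupings (seed 1) for the averaged effect and the interaction. Lists of the closing tests were compared with 10000 random lists matched for expression (seed 2).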

Results

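Messenger RNA was sequenced from mouse brain endothelial cells at 4 stages: embryonic stage E15.5, postnatal days 5 (P5) and 9 (P9), and adult. The series asked how the transcription factor Sox17 acts in the brain endothelium, in relation to canonical Wnt signalling and the tightness of the blood-brain barrier. Dissociated brain cells were depleted of CD45-positive leukocytes and captured on CD31-coated beads. All animals carried floxed Sox17 alleles and received tamoxifen. Animals with the endothelial driver Cdh5(PAC)-CreERT2, a recombinase that tamoxifen activates, are called KO, and animals without it wt. Each genotype had 3 libraries at each stage, 24 in all. Depth ranged from 12301779 to 19830600 counts per library, and 20147 to 22600 genes had at least 1 count. A count of 0 in 1 library allowed a level of up to 0.151 to 0.244 CPM, the count scaled to the library size, and intervals and floors cover counting error only. P5 and P9 had tamoxifen at postnatal day 1, E15.5 and adults other schedules. E15.5 and P5 had 1 dissociation kit, P9 and adult another. Comparisons of stages also compared time since tamoxifen, schedules or kits. No batch is named in the labels.

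Across the 17159 genes tested, Pearson's r between replicates of a group ranged from 0.971 to 0.99. The first and second principal components held 46.6% and 33.4% of the variance and separated the stages. The third held 4.92%, and on it the 3 P9 KO libraries lay between 58.3 and 65.3 while no other library exceeded 9.3.

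Sox17 (ENSMUSG00000025902, mm10 chromosome 1, 4490931 to 4497354, minus strand), an endothelial transcription factor of the SoxF group, was lower in every KO library than in any wt library of its stage. Its level fell from 90.5 ± 15.4 to 9.13 ± 1.3 CPM at E15.5 (SD, n = 3), from 277 ± 43.2 to 16.7 ± 2.11 at P5, from 333 ± 21.2 to 23.4 ± 4.18 at P9 and from 297 ± 21.8 to 52.7 ± 28.1 in adults. The KO level was 10.1%, 6.01%, 7.01% and 17.8% of wt, and the adult KO libraries held 57.3, 22.5 and 78.2 CPM. The log2 fold changes were -3.31 ± 0.28 (SE; adjusted p 1.7e-07), -4.06 ± 0.28 (4.7e-09), -3.83 ± 0.28 (4.5e-10) and -2.5 ± 0.26 (8.6e-06), and they differed between stages (interaction adjusted p 0.012). Counts were summed over the whole gene, so transcripts with recombined exons are included.

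**Figure D1:**
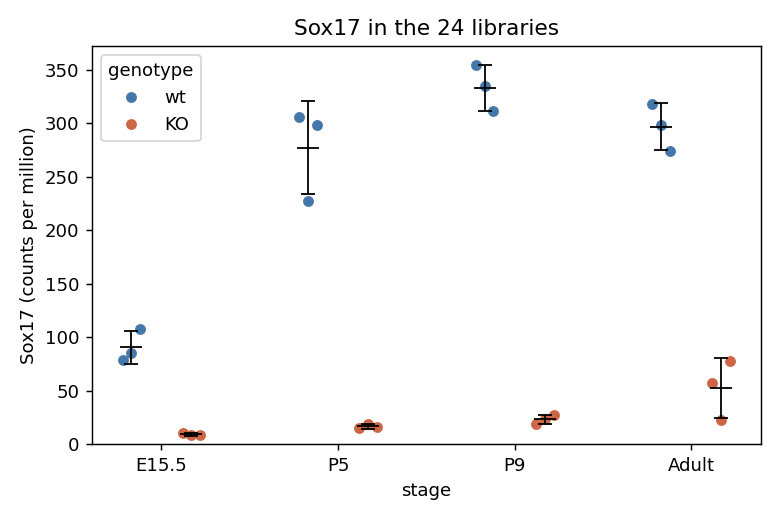
Sox17 in CPM on the vertical axis against stage, with 1 point per library and bars for the mean and SD of 3 libraries. Every KO library lies below every wt library of its stage, and the adult KO libraries, at 22.5 to 78.2 CPM, spread most among the KO groups.

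The next neighbouring protein-coding gene, Rp1 (ENSMUSG00000025900, chromosome 1, 4290846 to 4409241, minus strand), a photoreceptor microtubule protein gene, rose at every stage. Rp1 went from 1.22 to 13.7 ± 2.25 CPM at E15.5 (log2 3.49), 2.19 to 60.6 ± 5.03 at P5 (4.77), 1.81 to 58.7 ± 1.91 at P9 and 0.719 to 40.6 ± 2.87 in adults (5.82). Esr1 (ENSMUSG00000019768, chromosome 10), the estrogen receptor gene, also rose at every stage, from 0.266 to 10.6 ± 3.78 CPM at E15.5 (log2 5.32), 0.966 to 19.7 ± 0.952 at P5 (4.34), 0.929 to 24 ± 7.26 at P9 and 0.998 to 12.7 ± 3.21 in adults (3.66). These 2 genes and Sox17 were the only 3 called at all 4 stages.

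The E15.5 comparison asked how KO and wt differ in the embryonic brain endothelium. Interferon-induced genes formed most of the largest rises: Isg15, a ubiquitin-like modifier, went from 2.61 ± 1.59 to 20.3 ± 3.6 CPM (SD, n = 3). Isg15, Ifit1, Ifi44, Usp18, Oas1a, Oasl1, Irf7 and Rtp4, all induced by interferon, rose by 2.11 to 3.15 log2 (adjusted p 0.00011 to 0.015). The largest falls after Sox17 were Tubb1, the platelet beta-tubulin (-2.73 ± 0.47, adjusted p 0.0032), and genes of red cells. Hbb-bs, an adult beta-globin, fell from 1070 ± 202 to 227 ± 33.9 CPM, Hbb-bt, Hba-a2 and Hba-a1 by -1.87 to -2.32 log2, and the haem synthesis gene Alas2 by -2.22. Treml1 of platelets (-1.65), Fbln5, an elastic fibre protein of arteries (-1.45), and Lyz2 of myeloid cells (-1.43) also fell. Together 94 genes passed in edgeR, 72 higher and 22 lower, 857 had an unadjusted p under 0.05, and 43 of the 94 were called without any 1 of the 6 libraries. Oas1a (adjusted p 0.074), Oasl1 (0.14), Treml1 (0.13) and Lyz2 (0.078) lost their calls without wt library 1. Treml1 (0.2) and Lyz2 (0.091) did so without wt library 2. Oas1a (0.099), Oasl1 (0.14) and Treml1 (0.091) did so without wt library 3. Treml1 (adjusted p 0.24) and Lyz2 (0.062) lost their calls without KO library 1. Oasl1 (0.11), Treml1 (0.32) and Lyz2 (0.098) did so without KO library 2. Calls ended for Ifit1, Ifi44, Oas1a, Oasl1, Irf7, Treml1, Fbln5 and Lyz2 in a fit of the 6 compared libraries alone (adjusted p 0.066 to 0.39), and for Treml1 (0.063) with robust limma-trend, and for Oas1a (0.17), Oasl1 (0.15) and Fbln5 (0.21) without both E15.5 libraries numbered 3.

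The interferon response list had 13 of 20 genes higher at E15.5 and 18 adjusted over the list alone, among them Bst2, a membrane restriction factor (1.77 ± 0.22), with a median log2 fold change of 1.44 (camera adjusted p 7.9e-82; adjusted p = 0.0021 with estimated correlation). The endothelial-to-mesenchymal list moved up with Ly6a, the Sca-1 antigen gene (2.03 ± 1.26 to 7.76 ± 0.955 CPM; list adjusted p 3.7e-06, adjusted p = 0.015 with estimated correlation). Hypoxia and glycolysis moved up with adrenomedullin, Adm (1 ± 0.21), the 1 called of its 18 genes, and 5 adjusted over the list alone (adjusted p = 0.033 with estimated correlation). Angpt2, the Tie2 ligand of sprouting vessels, rose from 13.7 ± 2.67 to 33.4 ± 9.22 CPM in the tip cell and angiogenic list (adjusted p 2.1e-07; adjusted p = 0.087 with estimated correlation). Venous genes moved up, 2 of 17 called, Tmem252 (0.84) and the haemostasis gene Vwf (0.67) (adjusted p 5.4e-06; adjusted p = 0.072 with estimated correlation). Arterial genes moved down with Fbln5 called and 5 adjusted over the list alone (median -0.19, adjusted p 6.7e-06; adjusted p = 0.087 with estimated correlation). Smad6, a BMP inhibitor (1.24 ± 0.21), rose in the TGF-beta and BMP list (adjusted p 4e-04; adjusted p = 0.12 with estimated correlation), which did not pass without KO library 1 (0.091). Hmox1, haem oxygenase (1.22 ± 0.16), rose in the flow-responsive list (0.0058; adjusted p = 0.15 with estimated correlation), which did not pass without wt library 1 (0.13), wt library 3 (0.11) or KO library 1 (0.14). Csf1 (0.82) was the 1 called gene of the inflammatory list (4.2e-06; adjusted p = 0.12 with estimated correlation). Cell cycle (median 0.22; adjusted p = 0.13 with estimated correlation) and matrix lists (0.1; adjusted p = 0.4 with estimated correlation) passed upward at the preset correlation without a called gene. The matrix list did not pass without wt library 3 (0.14) or KO library 1 (0.64). The dissociation list passed downward (-0.14; adjusted p = 0.43 with estimated correlation) but turned upward without wt library 3 (0.83) and did not pass without both E15.5 libraries numbered 3 (1). In the SoxF list Sox17 alone set a downward call (mean -0.9, median 0.18; adjusted p = 0.015 with estimated correlation), which did not pass without KO library 3 (0.067). Adm (adjusted p 0.13), Angpt2 (0.13), Tmem252 (0.072), Vwf (0.21) and Csf1 (0.11) lost their calls without wt library 1. Adm (0.064) and Angpt2 (0.092) did so without wt library 2. Adm (0.08), Tmem252 (0.051), Vwf (0.17) and Csf1 (0.093) did so without wt library 3. Adm (adjusted p 0.14), Angpt2 (0.057), Tmem252 (0.054), Vwf (0.2) and Csf1 (0.082) lost their calls without KO library 1. Adm (0.057), Angpt2 (0.11) and Vwf (0.061) did so without KO library 3. There was no call for Ly6a, Adm, Angpt2, Tmem252, Vwf, Fbln5, Smad6 and Csf1 in a fit of the 6 compared libraries alone (adjusted p 0.054 to 0.45), nor for Adm, Angpt2, Tmem252, Vwf, Fbln5 and Csf1 without both E15.5 libraries numbered 3 (adjusted p 0.091 to 0.28).

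Wnt and barrier genes did not pass at E15.5. The medians were -0.08 for Wnt targets (adjusted p 0.94), 0 for Wnt receptors and effectors (0.91), 0.01 for junctions (0.66), -0.09 for barrier transporters (0.083), 0.15 for caveolae and vesicle genes (0.15), -0.07 for the Notch pathway (0.12) and 0.06 for endothelial identity (0.14), where Clec14a rose by 0.82. Values of named members were 0.15 for Lef1 and -0.09 for Axin2, both Wnt-responsive, -0.29 for the claudin Cldn5, 0.34 for the diaphragm protein Plvap, 0.21 for the glucose transporter Slc2a1, -0.32 for the lipid transporter Mfsd2a, 0.22 for Cdh5 and 0.13 for Pecam1. The other SoxF genes had values of 0.43 for Sox7 (adjusted p 0.12, 0.044 with DESeq2 and 0.028 without wt library 2) and 0.18 for Sox18. Red cell markers fell in sum from 3160 ± 520 to 1100 ± 329 CPM, 5 of 9 genes called and 6 lower and 2 higher adjusted over the list alone (adjusted p 3.8e-46; adjusted p = 6.7e-05 with estimated correlation), and leukocyte markers other than microglia by a median of -0.49 (0.0015; adjusted p = 0.34 with estimated correlation). Clec14a did not pass without wt library 3 (0.082), without KO library 1 (0.086), without both E15.5 libraries numbered 3 (0.12) or in the 6 libraries alone (0.19).

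At P5 the largest rises beside Rp1 and Esr1 included targets of p53 and stress genes. Eda2r, the ectodysplasin A2 receptor gene, went from 0.767 ± 0.121 to 16.9 ± 8.34 CPM (SD, n = 3; log2 4.44 ± 0.42) and Phlda3, an Akt inhibitor, from 4.64 ± 0.341 to 40.6 ± 16.6 (3.12 ± 0.29). Gdf15, a stress cytokine (2.87 ± 0.59), Prrg4, a Gla-domain membrane protein (2.63), Dcxr, a sugar reductase (2.08), Ptgs2, cyclooxygenase 2 (2.87 ± 0.223 to 11.6 ± 0.964 CPM), the long noncoding RNA Pvt1 (1.79) and the carboxylesterase Ces2e (1.71) also rose. The falls included arterial genes: Gkn3, an arterial secreted protein, fell from 6.96 ± 0.842 to 0.564 ± 0.432 CPM, the gap junction gene Gja5 from 16.8 ± 3.55 to 4.68 ± 0.652 and the growth factor Vegfc from 42.9 ± 2.69 to 19.4 ± 1.72. Osteopontin, Spp1 (-2.44), brachyury, T (-1.97), the antiangiogenic Serpinf1 (-1.42), Tmem100, a target of BMP signalling (-1.33), the phosphatase Alpl (-1.27) and Prr18 (-1.11) fell as well. In edgeR 91 genes passed, 68 higher and 23 lower, 1326 had an unadjusted p under 0.05, and 29 of the 91 were called without any 1 of the 6 libraries. Gdf15 (adjusted p 0.087), Prrg4 (0.1), Ces2e (0.069), Spp1 (0.33) and Alpl (0.16) lost their calls without wt library 1. Gdf15 (0.1), Prrg4 (0.072) and Pvt1 (0.058) did so without wt library 2. Gdf15 (0.075), Prrg4 (0.064), Pvt1 (0.062) and Alpl (0.18) did so without wt library 3. Gdf15 (adjusted p 0.096), Prrg4 (0.15), Pvt1 (0.078), Ces2e (0.082), Spp1 (0.22) and Alpl (0.25) lost their calls without KO library 1. Spp1 (0.12) did so without KO library 2. Gdf15 (0.11), Pvt1 (0.06), Spp1 (0.071) and Alpl (0.18) did so without KO library 3. No call remained for Alpl (0.16) with robust limma-trend.

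Arterial genes fell as a list at P5, 4 of 25 over all genes and 10 adjusted over the list alone (median -0.25, adjusted p 3.5e-13; adjusted p = 0.013 with estimated correlation). The interferon list rose with Bst2 called (0.91 ± 0.2) and 19 adjusted over the list alone (median 0.9, adjusted p 9.2e-27; adjusted p = 0.041 with estimated correlation). The inflammatory list moved up with Ptgs2 called and 9 higher adjusted over the list alone (5.2e-08; adjusted p = 0.072 with estimated correlation). Cell cycle passed upward without a called gene (median 0.24; adjusted p = 0.19 with estimated correlation). Endothelial identity, with Clec14a called (0.76), passed upward at a median of 0.06 (adjusted p = 0.64 with estimated correlation), and hypoxia at 0.08, which was -0.02 with scaling to endothelial identity genes (adjusted p = 0.4 with estimated correlation). Identity did not pass without wt library 1 (0.076), wt library 3 (0.47), KO library 2 (0.072) or KO library 3 (0.11), nor hypoxia without wt library 1 (0.2) or KO library 3 (0.19). The Notch pathway passed downward without a called gene (median -0.06; adjusted p = 0.24 with estimated correlation) but not without wt library 1 (0.17), KO library 2 (0.075) or KO library 3 (0.11). SoxF passed downward by Sox17 alone (mean -1.14, median 0.3; adjusted p = 0.013 with estimated correlation). Bst2 lost the call without each of the 6 libraries (adjusted p 0.068 to 0.24), and Clec14a (0.053 to 0.16) without library 1 or 3 of wt or KO. Calls ended for Bst2 (0.078) with robust limma-trend.

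The remaining lists did not pass at P5: Wnt targets (median -0.02, adjusted p 0.86), where the growth factor binding gene Fgfbp1 rose (0.91), Wnt receptors (-0.08, 0.055), junctions (0.01, 0.58), barrier transporters (0.05, 0.11), caveolae (0.05, 0.92), venous (0.05, 0.22), tip cell (0.03, 0.12), matrix (-0.08, 0.083), where Col18a1 of basement membrane fell (-0.72), TGF-beta and BMP (0, 0.86), flow-responsive (-0.04, 0.054), endothelial-to-mesenchymal (0.06, 0.32), where Ly6a rose (1.32), and dissociation (-0.05, 0.86). Values of named members were 0.06 for Lef1, 0.04 for Axin2, -0.02 for Cldn5, 0.24 for Plvap, 0.41 for Slc2a1, -0.28 for Mfsd2a, 0.25 for Cdh5, 0.05 for Pecam1, 0.34 for Sox7 and 0.3 for Sox18. Smooth muscle markers had a median of -0.47 with 1 gene lower (adjusted p 0.001; adjusted p = 0.43 with estimated correlation), fibroblast markers -0.3 (0.021; 0.85 so estimated) and markers of oligodendrocyte precursors -0.35 (0.037; 0.73 so estimated) with none. Fgfbp1 (adjusted p 0.06 to 0.3) lost the call without library 1 or 3 of wt or KO, and Col18a1 (0.074 to 0.17) without wt library 1 or 2 or KO library 1. There was no call for Fgfbp1 (0.065) and Ly6a (0.056) with robust limma-trend, nor for Fgfbp1 (0.088) with scaling to endothelial identity genes.

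At P9 the KO libraries differed from wt in 4809 genes, 28% of those tested, 2312 higher and 2497 lower. Doc2b, a calcium sensor of exocytosis, rose from 1.32 ± 0.465 to 162 ± 50.1 CPM (SD, n = 3), Hif3a, a hypoxia-inducible factor subunit, from 2.66 ± 0.602 to 244 ± 19.8, and Igfbp3, which binds insulin-like growth factors, from 45.2 ± 3.76 to 2220 ± 552. The amino acid oxidase gene Lao1 (6.16 log2), Vwa2 of the matrix (6), the kinase Map3k6 (5.82), Clca3a1 (5.62), the transcription factor Zbtb16 (5.51) and the acute-phase lipocalin Lcn2 (5.32; 3.57 to 143 ± 148 CPM) rose, and Etnppl, a phospholyase of astrocytes, had 161 counts against 1, a ratio of 165 (95% counting interval 29.3 to 6570). T fell by -4.14 log2, Gkn3 by -4.09 and Cbln2, a synapse organiser, from 20.9 ± 0.795 to 2.36 ± 0.53. Slfn9 (-3), the collagen receptor Itga2 (-2.85), the protease Adamts8 (-2.84), the lipoxygenase Alox12 (-2.72), Allc (-2.72) and Cd83 (-2.65) also fell. Adjusted p for these 10 rises and 9 falls was at most 2e-04, and 2874 of the 4809 genes were called without any 1 of the 6 libraries.

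All 26 cell cycle genes fell at P9, by a median of -1.83 (adjusted p 1.1e-56; adjusted p = 0.0013 with estimated correlation); the spindle gene Tpx2 went from 74.3 ± 7.03 to 16.7 ± 1.61 CPM, with Ccna2 (-2.33), Top2a (-2.05) and Mcm4 (-1.61). All 17 genes of the dissociation and stress list rose (median 1.13, adjusted p 2.6e-11; adjusted p = 0.054 with estimated correlation), among them Btg2 (2.04), Dusp1 (1.65), Zfp36 (1.47) and Egr1 (0.99). Flow-responsive genes rose, 6 of 11 with 1 fall (median 0.67, adjusted p 7.8e-05; adjusted p = 0.054 with estimated correlation): Ptgs2 went from 4.15 ± 0.504 to 108 ± 30.3 CPM and the vasoconstrictor Edn1 rose by 1.86, while Kdr fell (-0.44). Inflammatory genes had 9 rises and 1 fall (median 1.38; adjusted p = 0.19 with estimated correlation), with Nfkbia up (1.06) and Madcam1 down (-1.57). Hypoxia genes had 8 rises and 1 fall (0.45; adjusted p = 0.16 with estimated correlation), with Adm (1.57), Ndrg1 (1.84) and Bnip3 (1.41). Tip cell genes had 11 rises and 3 falls (0.39; adjusted p = 0.32 with estimated correlation); Angpt2 went from 96.5 ± 8.52 to 650 ± 213 CPM and the guidance receptor Unc5b fell (-1.62). The TGF-beta and BMP list had 9 rises and 1 fall, with Atoh8 (1.65), Smad1 (0.7) and Bmp4 (1.35) (median 0.46; adjusted p = 0.24 with estimated correlation), and did not pass without KO library 2 (0.054). With scaling to endothelial identity genes, rises and falls were 11 and 0 for dissociation, 5 and 2 for flow-responsive, 6 and 3 for hypoxia, 7 and 5 for tip cell, and 5 and 1 for TGF-beta and BMP genes.

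Arterial genes moved down at P9, 10 lower and 5 higher, 13 and 3 when scaled to endothelial identity genes (median -0.2, adjusted p 0.0032; adjusted p = 0.22 with estimated correlation); Vegfc fell from 33.2 ± 1.55 to 7.03 ± 1.61 CPM and the connexin Gja4 by -2. Venous genes moved up, 7 higher and 3 lower, 7 and 5 so scaled, with Il1r1 (1.78) up and Prcp (-1.17) down (median 0.25; adjusted p = 0.31 with estimated correlation). Barrier transporters had 10 rises and 4 falls with a median of 0.2, but 8 and 7 with a median of -0.01 when scaled to endothelial identity genes (adjusted p 0.0065; adjusted p = 0.54 with estimated correlation). Slc2a1 rose from 1410 ± 67.9 to 5440 ± 470 CPM, the efflux genes Abcc4 (1.43) and Abcg2 (0.85) rose, and Mfsd2a fell from 1440 ± 24.1 to 1050 ± 140 and Slc38a5 by -1. Junction genes had 7 rises and 1 fall, but 2 and 3 so scaled (adjusted p 0.1); Cldn5 rose from 5630 ± 190 to 7860 ± 1600 CPM, Ocln (0.6) and Esam (0.52) rose and Cgnl1 fell (-0.48). Wnt targets had 2 rises and 4 falls (median 0.05, -0.17 so scaled; adjusted p 0.86): Fgfbp1 rose (2.31), Nkd1 (-1.11), Tnfrsf19 (-0.64) and Lef1 (126 ± 22 to 86.1 ± 10.1 CPM) fell, and Axin2 had a value of 0.09 (0.68). Wnt receptors and effectors had 5 rises and 2 falls, but 1 and 3 so scaled (adjusted p 0.38), with the receptor Fzd4 (1.13) up and Ctnnb1 (-0.52) and Dkk2 (-1.29) down. Caveolae genes had 1 rise, Plvap from 9.38 ± 0.998 to 19.2 ± 2.3 CPM, and 4 falls, among them Ehd2 (-0.66), Emp1 (-0.82) and Cav1 (-0.51), 0 and 5 so scaled (adjusted p 0.36). Plvap (adjusted p 0.057) and Cav1 (0.077) lost their calls without wt library 1. Plvap (0.071) and Cav1 (0.061) did so without wt library 2. Mfsd2a (adjusted p 0.07) and Cldn5 (0.091) lost their calls without KO library 2. Plvap (0.064) and Cav1 (0.12) did so without KO library 3. No call remained for Cldn5 (0.053) in a fit of the 6 compared libraries alone, nor for Cldn5 (0.12) and Plvap (0.059) with scaling to endothelial identity genes.

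Endothelial identity had 6 rises and 5 falls at P9 (adjusted p 0.083); Clec14a rose from 152 ± 15.7 to 675 ± 53.3 CPM, Robo4 (1.04) and Egfl7 (0.75) rose and Cd34 fell (-0.63). Values were 0.18 for Cdh5, 0.15 for Pecam1, 0.08 for Sox7 and 0.58 for Sox18 (adjusted p 0.056, 0.021 with DESeq2 and 0.035 without KO library 3). The Notch pathway had 3 rises and 1 fall, but 0 and 3 with scaling to endothelial identity genes (adjusted p 0.57), with Dll4 (0.48) up and Heyl (-1.13) down. The matrix list had 3 rises and 3 falls, 3 and 6 so scaled (0.49): Col18a1 fell from 535 ± 3 to 90 ± 7.66 CPM and Col15a1 by -2.1, while Fn1 rose (1.09). The endothelial-to-mesenchymal list had 3 rises and 4 falls, 2 and 4 so scaled (median -0.34, mean -0.05, test upward; adjusted p 0.78), with Ly6a (2.06) up and Acta2 (-1.86) down. The interferon list had 3 falls, 6 so scaled, with Oas1a (-1.46), Oasl2 (-0.91) and Gbp3 (-0.64) (adjusted p 0.19), and SoxF did not pass (mean -1.06, median 0.08; 0.1). Among lists that did not pass, the median differed in sign from the mean or the test for Wnt targets at E15.5, P5 and P9, caveolae at P5 and in adults, flow-responsive, TGF-beta and dissociation genes at P5, matrix at P9 and in adults, and Wnt receptors, identity and interferon genes in adults. Heyl (adjusted p 0.059), Oasl2 (0.078) and Gbp3 (0.066) lost their calls without wt library 1. Oasl2 (0.062) and Gbp3 (0.13) did so without wt library 2. Heyl (0.051) did so without wt library 3. Heyl (adjusted p 0.076), Oasl2 (0.081) and Gbp3 (0.053) lost their calls without KO library 1. Oasl2 (0.13) and Gbp3 (0.15) did so without KO library 3. Calls ended for Dll4 (0.088) with scaling to endothelial identity genes.

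Pericyte markers at P9 fell in sum from 3750 ± 574 to 1620 ± 686 CPM, 9 of 12 called (adjusted p 0.00056; adjusted p = 0.85 with estimated correlation), and smooth muscle markers from 194 to 69.7, 5 of 7 called (adjusted p = 0.43 with estimated correlation). Fibroblast markers had 7 falls and 1 rise (820 to 480 CPM; adjusted p 0.061). Astrocyte markers rose from 632 ± 46.6 to 1160 ± 239 CPM, 8 of 10 called, 4 when scaled to endothelial identity genes (adjusted p 0.00016; adjusted p = 0.43 with estimated correlation), and markers of peripheral and lymphatic endothelium from 27.2 to 77.5, 3 of 5 called (0.0057; adjusted p = 0.11 with estimated correlation). With scaling to endothelial identity genes, chosen after seeing the data, the P9 split was 1063 higher and 4094 lower, and with DESeq2 size factors 2867 and 2089. That scaling moved the median of all genes at P9 from 0.02 to -0.19.

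**Figure D2:**
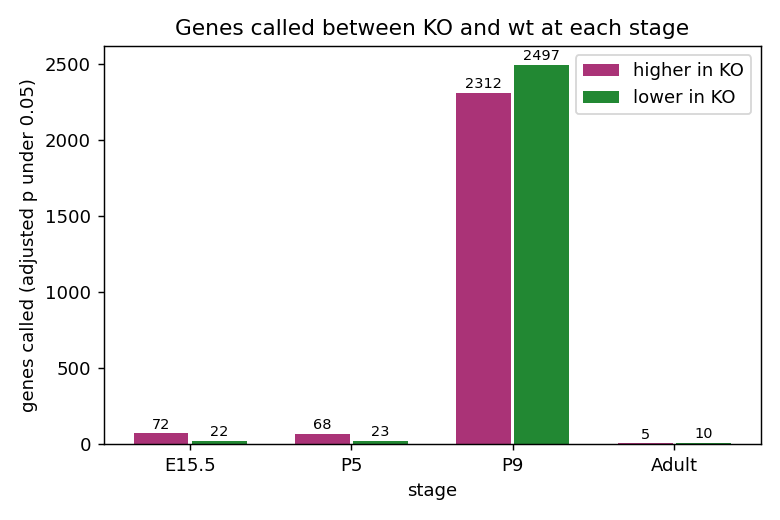
Number of genes called between KO and wt on the vertical axis at each stage, higher and lower in KO as separate bars. P9 has 2312 higher and 2497 lower genes, a split that is 1063 and 4094 with scaling to endothelial identity genes, and the adult stage has 5 and 10.

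**Figure D3:**
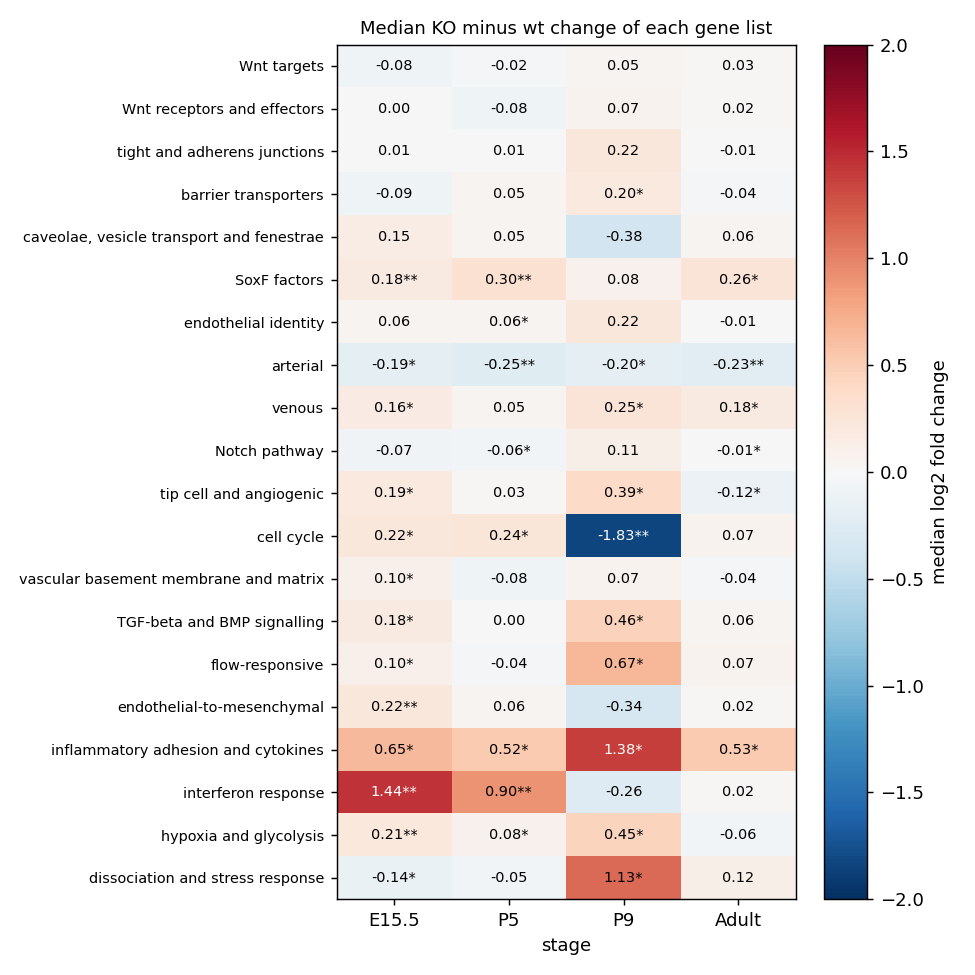
Median log2 fold change, KO over wt, of each gene list at each stage, as colour and printed value, with 1 star for a list past 0.05 at the preset correlation and a pair of stars where it also passed with estimated correlation. The cell cycle list lies at -1.83 at P9 and the interferon list at 1.44 at E15.5, and the starred SoxF lists moved down by Sox17 although their medians are positive.

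In adults 15 genes passed in edgeR, 5 higher and 10 lower, and 604 had an unadjusted p under 0.05. Gkn3 fell from 44.4 ± 5.76 to 14.8 ± 4.9 CPM (SD, n = 3), Alox12 from 40.3 ± 1.52 to 16.7 ± 1.18, the kinase Zap70 from 29.1 ± 1.66 to 12.8 ± 2.36, the Notch ligand Dll4 from 139 ± 5.08 to 82.5 ± 8.33 and the receptor Notch4 from 217 ± 14.8 to 143 ± 16.1. Gstm7, a glutathione transferase (-0.66), Prom1 (-0.59), Lrrc49 (-0.58) and the transcription factor Mecom (-0.54) also fell. Ptgs2 rose from 8.8 ± 1.06 to 22.2 ± 6.89 CPM and Fam196a by 2.13 ± 0.39. The remaining called gene, the uroplakin Upk1a, chosen after its values were seen, rose from 0.267 ± 0.167 to 1.4 ± 0.488 CPM (2.4 ± 0.43, adjusted p 0.021). Of the 15, 4 were called without any 1 of the 6 libraries. Alox12 (adjusted p 0.054 to 0.13), Gstm7 (0.12 to 0.35) and Mecom (0.071 to 0.36) lost their calls without any library but KO library 3, Gkn3 (0.058 to 0.33) without any but KO library 1, and Notch4 (0.064 to 0.24) without any but KO library 2. Ptgs2 (0.05 to 0.13), Fam196a (0.088 to 0.31) and Dll4 (0.05 to 0.12) lost theirs without each wt library, and without KO library 3, 2 and 1. Prom1 (0.056 to 0.11) and Lrrc49 (0.06 to 0.13) did so without wt library 1 or 2 or KO library 1 or 2, and Upk1a (0.18 to 0.22) without wt library 2 or 3 or KO library 1. There was no call for Upk1a (0.16) in a fit of the 6 compared libraries alone, nor for Gkn3 (0.48) and Ptgs2 (0.13) with robust limma-trend, nor for Gkn3, Gstm7, Lrrc49, Mecom and Ptgs2 with scaling to endothelial identity genes (adjusted p 0.066 to 0.19).

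Adult arterial genes fell as a list, 3 of 25 over all genes and 7 adjusted over the list alone (median -0.23, adjusted p 7.4e-13; adjusted p = 0.013 with estimated correlation). Notch genes moved down with Dll4 and Notch4 called, 2 of 16 (0.0012; adjusted p = 0.1 with estimated correlation), and the tip cell list with Dll4 (6e-04; adjusted p = 0.24 with estimated correlation), which did not pass without wt library 1 (0.075). Inflammatory genes moved up with Ptgs2 (4e-04; adjusted p = 0.22 with estimated correlation) but did not pass without KO library 3 (0.073), and venous genes moved up (0.0041; adjusted p = 0.22 with estimated correlation) but did not pass without wt library 2 (0.085). SoxF passed downward by Sox17 (mean -0.59, median 0.26; 0.012; adjusted p = 0.081 with estimated correlation, 0.057 with scaling to endothelial identity genes). The other lists did not pass, among them Wnt targets (median 0.03), Wnt receptors (0.02), junctions (-0.01), barrier transporters (-0.04), caveolae (0.06), endothelial identity (-0.01), cell cycle (0.07), matrix (-0.04), TGF-beta and BMP (0.06), flow-responsive (0.07), interferon (0.02), hypoxia (-0.06) and dissociation (0.12). Values were -0.25 for Lef1, -0.02 for Axin2, -0.08 for Cldn5, 0.07 for Plvap, -0.03 for Slc2a1, -0.14 for Mfsd2a, 0.03 for Cdh5, -0.02 for Pecam1, 0.48 for Sox7 (adjusted p 0.2, 0.043 with DESeq2 and 0.046 without KO library 3) and 0.26 for Sox18. Adult markers of red cells had a median of -0.43 (0.00023; adjusted p = 0.34 with estimated correlation), of other leukocytes 0.76 (0.0029; 0.34 so estimated) and of microglia and macrophages 0.3 (0.037; 0.9 so estimated), and Dll4, Notch4 and Ptgs2 lost their calls without the libraries named with the adult gene list.

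**Figure D4:**
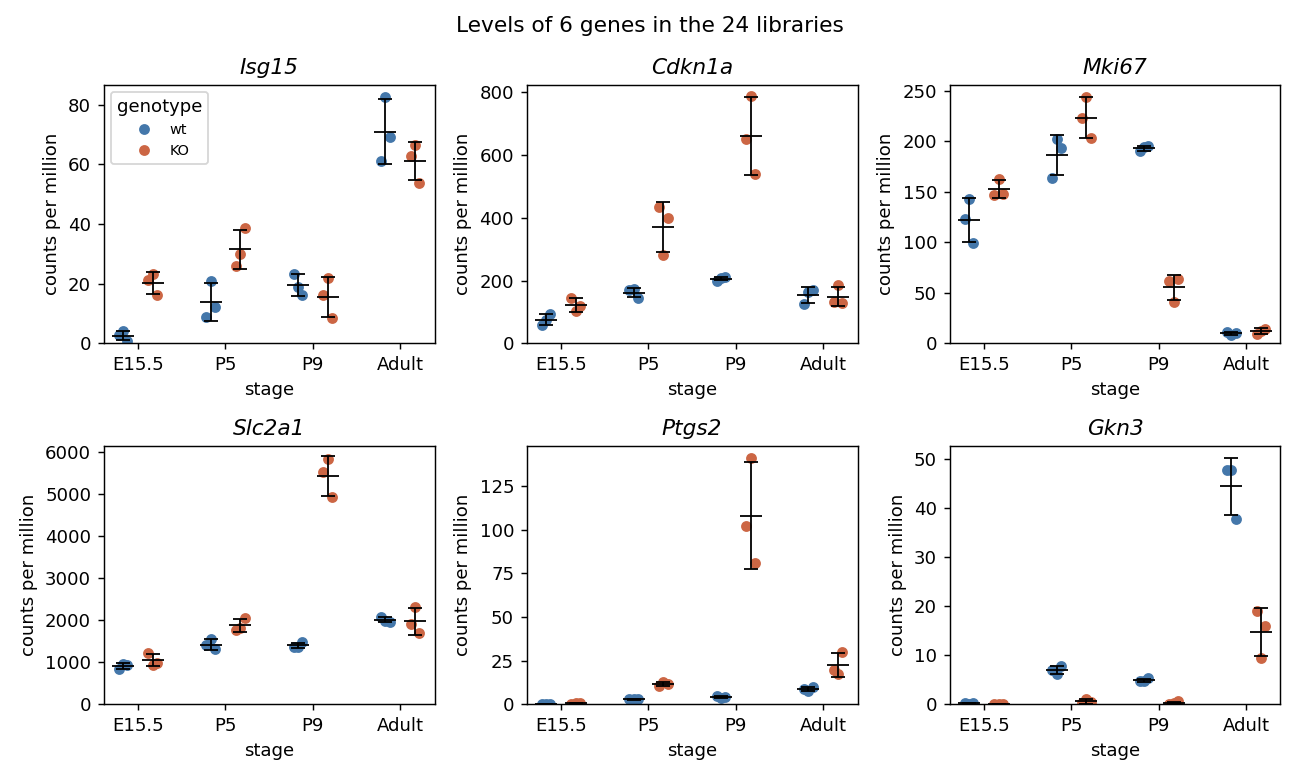
Levels of Isg15, Cdkn1a, Mki67, Slc2a1, Ptgs2 and Gkn3 in CPM against stage, with 1 point per library and bars for the mean and SD of 3 libraries. Slc2a1 at P9 rises from 1410 ± 67.9 to 5440 ± 470 CPM in KO, and Mki67, chosen like Cdkn1a after its values were seen, falls from 193 ± 2.69 to 55.6 ± 12.2.

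**Figure D5:**
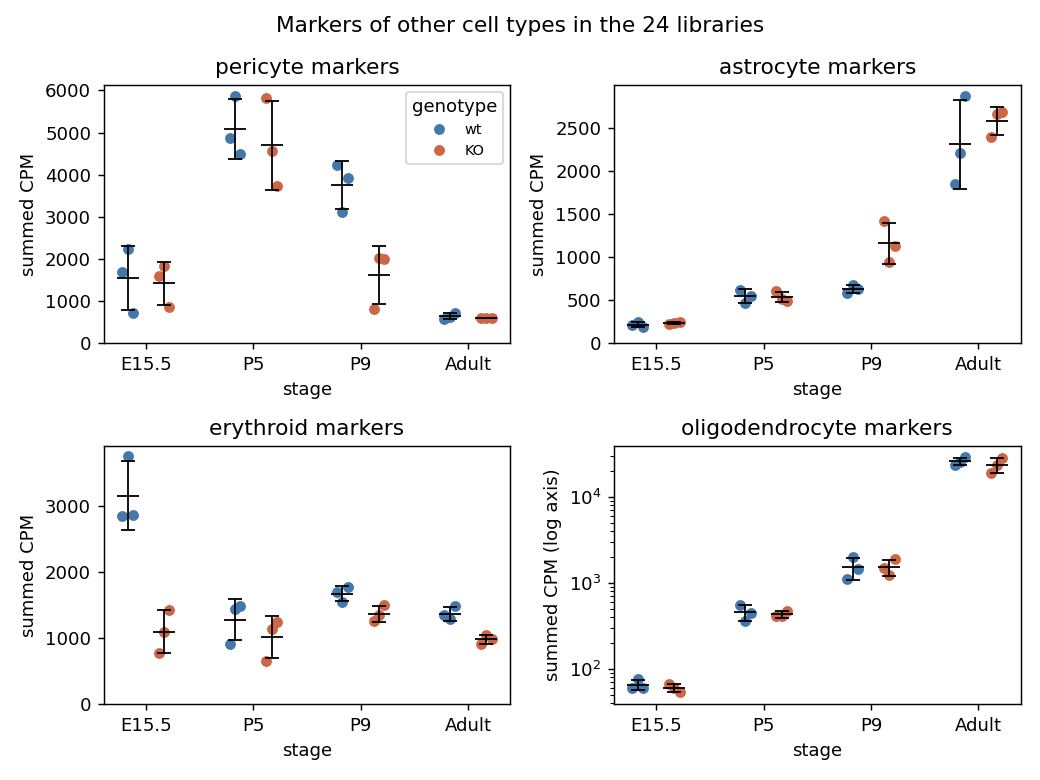
Summed CPM of markers of pericytes, astrocytes, red cells and oligodendrocytes against stage, with 1 point per library and bars for mean and SD of 3 libraries; the oligodendrocyte axis is logarithmic. Pericyte markers at P9 fall from 3750 ± 574 to 1620 ± 686 CPM in KO.

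Averaged over the 4 stages, 1487 genes passed, 823 higher and 664 lower, but 418 and 2021 with scaling to endothelial identity genes, and 982 of them in each of 24 fits without 1 library. Arterial genes fell, 11 of 25 with 1 rise (median -0.24, adjusted p 6.9e-15; adjusted p = 0.0098 with estimated correlation), among them Vegfc (-1.16 ± 0.08), the semaphorin Sema3g (-0.75), Gja5 (-1.47) and Gkn3 (-2.93). Inflammatory genes rose, 11 of 16 (median 0.97; adjusted p = 0.033 with estimated correlation), with Ptgs2 (2.33 ± 0.17), the adhesion molecule Icam1 (0.81) and Csf1 (0.42), and flow-responsive genes, 4 of 11, mostly by P9 (medians 0.1, -0.04, 0.67 and 0.07 by stage), with Hmox1 (0.52) (adjusted p = 0.033 with estimated correlation). Cell cycle genes fell, 17 of 26, by P9 alone, as their medians were positive at the other stages (adjusted p = 0.041 with estimated correlation), with Mcm2 (-0.44) and Tpx2 (-0.43). Interferon genes rose, 13 of 20, by E15.5 and P5, with medians of -0.26 at P9 and 0.02 in adults (median 0.51; adjusted p = 0.12 with estimated correlation), with Ifit1 (1.33). Venous genes had 7 rises and 1 fall at a median of 0.06 that was -0.04 when so scaled (adjusted p = 0.072 with estimated correlation). Tip cell, TGF-beta and BMP, hypoxia, dissociation, identity and endothelial-to-mesenchymal lists also passed upward (0.072 to 0.55 so estimated), and SoxF downward. Fgfbp1 (1.03), Slc2a1 (0.63), Clec14a (1.08), Angpt2 (1.17) and Sox7 (0.33) rose, and Mfsd2a (-0.3), the amino acid transporter Slc7a1 (-0.53) and Col18a1 (-0.83) fell. Values were 0.01 for Axin2, -0.15 for Lef1 (adjusted p 0.2, 0.014 so scaled), 0.02 for Cldn5, 0.42 for Plvap (0.099), 0.33 for Sox18 (0.07, 0.033 with DESeq2) and 0.08 for Pecam1. Averaged markers of red cells (median -0.73), smooth muscle (-0.49), pericytes (-0.36) and fibroblasts (-0.32) moved down and of astrocytes (0.24) up, with adjusted p of 0.11, 0.34, 0.85, 0.73 and 0.62 with estimated correlation.

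The effect of genotype differed between stages in 2325 genes (F test of the interaction). Between pairs of stages it differed in 2269 to 2708 genes for pairs with P9 and in 6 to 27 for other pairs. Slc2a1 (adjusted p 9.4e-08), Igfbp3 (2.1e-10), Tpx2 (4.1e-09), Col18a1 (1.5e-08) and Isg15 (9.8e-05) were among the genes with a stage-dependent effect, and Gja5 (0.46), Sox7 (0.28) and Mfsd2a (0.72) were not.

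Lists of called genes overlapped between stages more than the product of their sizes gives. E15.5 and P5 shared 15 rises and 3 falls, against 0.29 and 0.029, with none in opposite directions; the rises included Rp1, Esr1, Ly6a, Sp100 and Timp3, and the falls were Sox17, T and the decarboxylase gene Ddc. P5 and P9 shared 33 rises and 19 falls, against 9.2 and 3.3, with 10 opposite, E15.5 and P9 20 and 5, against 9.7 and 3.2, with 13 opposite, and P9 and adult 3 and 4, against 0.67 and 1.5, with 2 opposite. Adult shared 2 rises and 2 falls with E15.5, against 0.021 and 0.013, and 3 and 2 with P5, against 0.02 and 0.013. Those shared with adults were Rp1, Esr1 and the deleted gene Sox17 with Alox12 for E15.5, and the same 3 with Gkn3 and Ptgs2 for P5. Called at 3 stages were 8 genes, among them Apobec3, an antiviral deaminase, and Timp3, a protease inhibitor, both higher. Genes named from these overlaps were chosen after their values were seen. At E15.5, T lost the call without each of the 6 libraries (adjusted p 0.054 to 0.21), and Apobec3 without wt library 1 (0.12) or 3 (0.11) or KO library 1 (0.16). At P5, Apobec3 (adjusted p 0.059 to 0.14) lost the call without any library but wt library 2, Timp3 (0.053 to 0.21) without library 1 or 3 of wt or KO, and Ddc (0.12 to 0.18) without library 2 or 3 of wt or KO. In adults, Alox12, Gkn3, Ptgs2 and Lrrc49 lost their calls without the libraries named with the adult gene list. Across all tested genes, which are not independent replicates, the log2 fold changes of pairs of stages had Pearson correlations of 0.02 to 0.19. Set against the wt change from E15.5 to adult, which shares no library with them, the KO effects had Pearson and Spearman correlations across genes of 0.08 and 0.09 at P5 and of 0.05 and 0.05 at P9. Other splits of the same KO and wt libraries reached absolute Pearson correlations of 0.08 and 0.2.

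The wt libraries asked how the endothelial fraction changes with age. From E15.5 to P5, the barrier genes Slco1a4, an organic anion carrier (7.22 ± 0.31), and Slc16a1, the lactate carrier (7.21 ± 0.22), were among the 10 largest rises, beside the astrocyte genes Gfap (7.69), Gpr37l1 (7.65), Aqp4 (6.74) and Agt (6.86), and Mag (5.7) of myelin. The oligodendrocyte genes Mobp and Neu4 rose by counting ratios of 218 (74.2 to 1060) and 181 (49.7 to 1500). Falls were led by the embryonic globins Hba-x, at least 1920-fold, and Hbb-y (-8.78 log2), and by the neuronal factors Prdm12, at least 102-fold, Shox2, at a ratio of 469 (83.8 to 18600), Otp, Isl1 (-6.88) and Pou4f2. In edgeR 6215 genes were higher and 5220 lower, but 675 and 13669 with scaling to endothelial identity genes, which moved the median of all genes from 0.09 to -1.44. All 22 barrier transporters rose, but 12 rose and 4 fell so scaled (adjusted p = 0.032 with estimated correlation), and all 11 flow-responsive genes rose, but 3 and 1 so scaled (adjusted p = 0.032 with estimated correlation), with Klf4 (3.07) and Klf2 (3.05). Endothelial identity (21 of 21 higher; adjusted p = 0.099 with estimated correlation), junctions (14 of 18; adjusted p = 0.12 with estimated correlation), arterial (20 of 25; adjusted p = 0.12 with estimated correlation), tip cell (15 of 22; adjusted p = 0.22 with estimated correlation), matrix (16 of 18; adjusted p = 0.18 with estimated correlation), TGF-beta and BMP (13 of 19; adjusted p = 0.22 with estimated correlation), endothelial-to-mesenchymal (9 of 13; adjusted p = 0.051 with estimated correlation), caveolae (6 of 8; adjusted p = 0.31 with estimated correlation) and cell cycle (19 of 26; adjusted p = 0.56 with estimated correlation) moved up at the preset correlation, with medians of 0.51 to 1.51 that turned negative, -0.03 to -1.04, so scaled, for identity by construction.

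Wnt targets (12 of 15 higher; adjusted p = 0.19 with estimated correlation), venous (14 of 17; adjusted p = 0.12 with estimated correlation), inflammatory (11 of 16; adjusted p = 0.29 with estimated correlation), interferon (18 of 20; adjusted p = 0.42 with estimated correlation) and dissociation genes (14 of 17; adjusted p = 0.13 with estimated correlation) moved up from E15.5 to P5, with medians of 0.01, 0.08, 0.57, 0.8 and 0.69 so scaled. Cell cycle did not pass without E15.5 wt library 3 (0.063), P5 wt library 2 (0.08) or P5 wt library 3 (0.066), without both E15.5 libraries numbered 3 (0.071) or so scaled (0.95), nor did caveolae so scaled (0.14). Wnt receptors (median 0.18), SoxF (0.86), Notch (0.66) and hypoxia (0.31) did not pass, with medians of -1.37, -0.68, -0.89 and -1.24 so scaled. Notum (3.4) and Ccnd1 (2.43), both Wnt targets, Fzd4 (2.07), Cldn5 (1.99), Mfsd2a (1.82), Cgnl1 (2.22) and Flt1 (2.29) rose and Plvap fell (-1.1). Sox17 rose (1.61), but by 0.08 so scaled (adjusted p 0.78). Lef1 (0.8), Slc2a1 (0.64), Cdh5 (1.2), Pecam1 (1.3), Sox7 (0.86), Sox18 (0.65), Notch4 (1.13), Notch1 (1.18), Lrp5 (1.27), Tnfrsf19 (1.4), Ehd4 (1.29), Ehd2 (1.18), Pcna (1.03), Cdk1 (0.79), Mcm3 (0.82), Mcm2 (0.8), Bmpr2 (1.34), Nfkbia (1.03) and Eno1 (0.78) rose, and Axin2 had a value of 0.09, but all had negative values, -0.15 to -1.45, with scaling to endothelial identity genes. Sox18 did not pass without E15.5 wt library 3 (0.099) or P5 wt library 1 (0.059). All 11 neuron markers fell (median -2.41; adjusted p = 0.3 with estimated correlation), and pericyte markers (11 of 12 higher, but 1 higher and 1 lower so scaled; adjusted p = 0.56 with estimated correlation) and microglia markers (11 of 12; adjusted p = 0.44 with estimated correlation) rose. Markers of neural progenitors had 1 rise and 6 falls, of oligodendrocyte precursors 5 rises of 7 and of ependyma and choroid plexus 8 rises of 9 (adjusted p 0.39, 0.39 and 0.44 with estimated correlation). Markers of oligodendrocytes (8 of 9), astrocytes (8 of 10, but 4 up and 4 down so scaled) and smooth muscle (6 of 7, 3 so scaled) moved up and of red cells (8 of 9) down (0.3 to 0.35 so estimated).

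From P5 to P9, across the change of kit, wt libraries differed in 879 genes, 458 higher and 421 lower, but 149 and 459 with scaling to endothelial identity genes, and 215 of them in every fit without 1 library. The oligodendrocyte genes Ermn (4.12 ± 0.46), Mog (3.79), Hapln2 (3.25) and Mobp (3.11) and the microRNA gene Mir219a-2 (3.58) led the rises, and 8 of 9 oligodendrocyte markers rose (median 2.17; adjusted p = 0.00076 with estimated correlation). The macrophage genes F13a1 (-4.8) and C1qa (-3.38), Gckr, at a counting ratio of 86.9 (29.4 to 424), Fam71a (-5.02), Calb1 (-3.92) and Arhgef33 (-3.4) led the falls, and 8 of 12 microglia and macrophage markers fell (median -2.26; adjusted p = 0.025 with estimated correlation). The heat shock genes Hspa1b (2.98) and Hspa1a (2.72) rose while the immediate early genes Egr1 (-1.57) and Fos (-1.32) fell, 2 and 7 of the dissociation list (adjusted p = 0.3 with estimated correlation). Adm (1.18) and Ankrd37 (1.85) of hypoxia (adjusted p = 0.19 with estimated correlation), Smad7 (1.03), Sox18 (0.88), Dll4 (0.48), Lef1 (0.48) and Cxcr4 (0.79) rose, and Plvap (-1.61), Dll1 (-1.27), Col18a1 (-0.93), Col15a1 (-1.28), Klf4 (-0.84) and Rnf43 (-1.66) fell. Tip cell (adjusted p = 0.26 with estimated correlation) and SoxF (adjusted p = 0.12 with estimated correlation) moved up, and caveolae (adjusted p = 0.29 with estimated correlation), matrix (adjusted p = 0.46 with estimated correlation) and endothelial-to-mesenchymal (adjusted p = 0.19 with estimated correlation) moved down. Markers of smooth muscle (median -0.74), pericytes (-0.45), fibroblasts (-0.35), oligodendrocyte precursors (-0.57) and peripheral endothelium (-1.16) also moved down and of astrocytes (0.23), red cells (0.41) and other leukocytes (0.67) up, with adjusted p of 0.062 to 0.56 with estimated correlation. Without P5 wt library 2, caveolae (0.23), matrix (0.16) and endothelial-to-mesenchymal (0.072) did not pass. Barrier transporters moved up (adjusted p = 0.56 with estimated correlation) but not without P5 wt library 1 (0.061), P5 wt library 3 (0.2) or P9 wt library 2 (0.061), nor when so scaled (0.081). Values were 0.27 for Sox17, 0.34 for Sox7, 0 for Axin2, 0.07 for Cldn5, -0.02 for Slc2a1, 0.17 for Mfsd2a, -0.2 for Cdh5 and 0.17 for Pecam1. Lef1 (adjusted p 0.066) lost the call without P5 wt library 1. Sox18 (0.05), Dll4 (0.06), Lef1 (0.051) and Cxcr4 (0.086) did so without P5 wt library 2. Sox18 (0.13), Dll4 (0.14), Lef1 (0.19) and Cxcr4 (0.13) did so without P5 wt library 3. Sox18 (adjusted p 0.06), Dll4 (0.089), Lef1 (0.18) and Cxcr4 (0.11) lost their calls without P9 wt library 1. Sox18 (0.1), Dll4 (0.094), Lef1 (0.16) and Cxcr4 (0.086) did so without P9 wt library 2. Dll4 (0.055) did so without P9 wt library 3. No call remained for Lef1 (0.054) with DESeq2 size factors, nor for Dll4 (0.088), Lef1 (0.13) and Cxcr4 (0.066) with scaling to endothelial identity genes.

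From P9 to adult, 5294 genes were higher and 5191 lower, but 9730 and 1905 with scaling to endothelial identity genes, which moved the median from 0.02 to 0.65. All 26 cell cycle genes fell (median -3.87; adjusted p = 0.0043 with estimated correlation), with Cdk1 (-5.54 ± 0.16), and 15 of 18 matrix genes (-2.26; adjusted p = 0.032 with estimated correlation), with Lamb1 (-4.57) and Nid1 (-4.06). Tip cell genes fell, 15 of 22, with Apln (-3.51) and Aplnr (-5.03) (adjusted p = 0.054 with estimated correlation). The largest rises were Etnppl, at a ratio of 1670 (299 to 65900), RP23-63A19.1, at least 141-fold, D7Ertd443e, 557 (154 to 4600), Gabra6, 483 (86.3 to 19100), and RP24-187P11.2, 475 (84.9 to 18800). The largest falls were Cpa1, at least 68-fold, the adhesion gene Madcam1 (-7.87), the oxidase Nox4 (-6.87), Igf2bp3, at a ratio of 119 (40.5 to 580), and Dusp27 (-6.68). Interferon genes moved up, 18 of 20, with Ifit1 (3.84) (adjusted p = 0.5 with estimated correlation), and dissociation genes down, 14 of 17, with Egr1 (-2.75) (adjusted p = 0.23 with estimated correlation). Wnt targets (11 of 15 lower; adjusted p = 0.29 with estimated correlation), barrier transporters (15 of 22, with Tfrc at -2.57; adjusted p = 0.31 with estimated correlation), venous (11 of 17; adjusted p = 0.17 with estimated correlation), Notch (10 of 16; adjusted p = 0.29 with estimated correlation, 0.062 so scaled) and endothelial identity (17 of 21; adjusted p = 0.36 with estimated correlation) moved down. So scaled, Wnt targets were 5 higher and 9 lower, transporters 8 and 10, venous genes 4 and 8, Notch genes 5 and 6 and identity genes 5 and 6. Mfsd2a (-1.73), Sox7 (-1.25) and Hmox1 (-1.32) fell and Slc2a1 (0.52) and Plvap (0.9) rose. Cldn5 (-0.49), Cdh5 (-0.58), Pecam1 (-0.4), Emp1 (-0.63) and Pacsin2 (-0.3) fell, but were 0 to 0.34 with scaling to endothelial identity genes. Values were -0.17 for Sox17, 0.11 for Sox18, 0.19 for Lef1 (adjusted p 0.23, 9.9e-06 so scaled) and 0.33 for Axin2 (0.056, 1e-05 so scaled). All 9 oligodendrocyte markers rose (1520 to 25800 CPM in sum; adjusted p = 0.018 with estimated correlation) and all 12 pericyte markers fell (adjusted p = 0.39 with estimated correlation). Markers of microglia and macrophages (11 of 12, median 3.89), astrocytes (8 of 10), oligodendrocyte precursors (5 of 7) and ependyma (6 of 9) moved up and of fibroblasts (7 of 9) down (0.35 to 0.41 so estimated). Plvap (adjusted p 0.051) and Pacsin2 (0.074) lost their calls without P9 wt library 1. Plvap (0.068) did so without P9 wt library 2. Pacsin2 (0.086) did so without P9 wt library 3. Plvap (adjusted p 0.32) and Pacsin2 (0.052) lost their calls without Adult wt library 1. Emp1 (0.095) and Pacsin2 (0.095) did so without Adult wt library 2. Calls ended for Plvap (0.051) with robust limma-trend, and for Pacsin2 (0.068) without the low-count filter, and for Pacsin2 (0.088) with DESeq2, and for Pacsin2 (0.086) with DESeq2 size factors.

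From E15.5 to adult, 6046 genes were higher and 5890 lower, but 2436 and 11446 with scaling to endothelial identity genes, which moved the median from 0 to -1.02. The myelin genes Mog and Mobp had counting ratios of 28500 (5120 to 1130000) and 18400 (6310 to 89400), Klk6 and Etnppl rose at least 573-fold and 558-fold, and Gpr37l1 by 11.48 log2. Hba-x fell at least 1740-fold, Igf2bp1 at a ratio of 1090 (374 to 5310), Cpa1 at least 105-fold, and Tfap2d and Prdm12 at least 95.1-fold and 92.5-fold. All 26 cell cycle genes fell (median -3.39; adjusted p = 0.032 with estimated correlation). All 20 interferon genes rose (4.17; adjusted p = 0.26 with estimated correlation), with Gbp2 (5.27) and Irf7 (5.34). Barrier transporters (14 of 22 higher; adjusted p = 0.22 with estimated correlation) rose with Slco1a4 (9.66 ± 0.33), Abcb1a (3.49) and Slc19a3 (4.11). Flow-responsive genes (8 of 11; adjusted p = 0.12 with estimated correlation) rose with Thbd (3.19), and TGF-beta and BMP (12 of 19; adjusted p = 0.31 with estimated correlation), inflammatory (10 of 16; adjusted p = 0.42 with estimated correlation) and endothelial identity lists (18 of 21; adjusted p = 0.31 with estimated correlation) moved up, but transporters were 13 higher and 8 lower so scaled. Junctions (15 of 18, median 0.89; adjusted p = 0.22 with estimated correlation) and arterial genes (16 of 25, median 0.93; adjusted p = 0.24 with estimated correlation) moved up but had medians of -0.13 and -0.05 so scaled. Matrix genes (12 of 18 lower; adjusted p = 0.31 with estimated correlation) fell with Col18a1 (-3.52). Sox17 (1.71), Sox18 (1.64), Lef1 (1.46), Cldn5 (1.57), Slc2a1 (1.15) and Pecam1 (1.07) rose, Plvap fell (-1.81), and Sox7 had a value of -0.04 (adjusted p 0.74, 2.3e-09 so scaled). Axin2 (0.41), Cdh5 (0.42), Lrp5 (0.88) and Jag2 (0.87) rose and Mfsd2a had a value of 0.26, but all had values of -0.14 to -0.76 with scaling to endothelial identity genes. All 9 oligodendrocyte (adjusted p = 0.0078 with estimated correlation) and all 10 astrocyte markers (adjusted p = 0.11 with estimated correlation) rose. Markers of microglia and macrophages (11 of 12, median 3.95), ependyma (9 of 9), oligodendrocyte precursors (5 of 7) and smooth muscle (4 of 7) moved up and of red cells (9 of 9) and neurons (8 of 11) down (0.3 to 0.41 so estimated). Axin2 (adjusted p 0.13) lost the call without E15.5 wt library 3. Axin2 (adjusted p 0.095) lost the call without Adult wt library 1. There was no call for Axin2 (0.11) without both E15.5 libraries numbered 3, nor for Slc2a1 (0.22) and Pecam1 (0.62) with scaling to endothelial identity genes. Among the wt lists that did not pass, the median differed in sign from the mean or the test for hypoxia genes from E15.5 to P5, for Wnt targets, arterial and cell cycle genes from P5 to P9, for arterial, TGF-beta, flow-responsive, inflammatory and hypoxia genes from P9 to adult, and for Wnt receptors, venous and dissociation genes from E15.5 to adult.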

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

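The tests of mural cells, of Cre activity and of transcription into Rp1 were chosen only after the result was seen. The effect of genotype differed between stages in 2325 genes by the F test of the interaction. By pairs of stages it differed in 2708 genes for P9 against E15.5, 2695 for P9 against P5, 2269 for adult against P9, 27 for adult against E15.5, and 6 each for P5 against E15.5 and adult against P5. Of 100 regroupings of KO and wt within every stage, 4 gave as many interaction genes as the real one, itself counted (highest other 3120). For the averaged effect (1487 genes) 2 did so, and the highest other gave 1582. Both shares, under 0.05, argue against chance. Regroupings that kept the P9 groups were not set apart.

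The 10 splits of 6 libraries are too few for a share under 0.05. At E15.5, 2 of the 10 gave as many genes as the real split's 94. The highest other (179) set wt libraries 1 and 2 and KO library 1 against the others. Summed ependymal, fibroblast, leukocyte and peripheral endothelial markers followed it, and oligodendrocyte precursors in reverse. The rest did not: pericytes were 731.2 and 861.6 CPM in libraries numbered 3, 1595 to 2230 otherwise. Elsewhere only the real split gave as many genes: 91 at P5 (highest other 0), 4809 at P9 (1) and 15 in adults (1). For wt, E15.5 to P5 gave 11435, P5 to P9 879, P9 to adult 10485 and E15.5 to adult 11936 (highest other 0).

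Among named genes, with the adjusted p of the interaction, the effect of genotype differed between stages as follows. Timp3 (1.2e-11), Doc2b, Hif3a and Igfbp3 (2.1e-10), Tpx2 (4.1e-09), Zbtb16 (6.2e-09), Btg2 (7.5e-09), Col18a1 (1.5e-08), Ccna2 (1.7e-08), Top2a (2e-08), Map3k6 (2.3e-08), Mcm4 (5.2e-08), Slc2a1 (9.4e-08), Adamts8 (1.7e-07) and Mki67 (4.7e-07) differed. Trp53inp1 (6.4e-07), Ptgs2 (6.5e-07), Vwa2 (1.5e-06), Edn1 (1.8e-06), Cbln2 (2.4e-06), Slfn9 and Ddit4 (2.8e-06), Abcc4 (6.2e-06), Lrrc49 (8.9e-06), Hbb-bs (9.1e-06), Tmem100, Zap70 and Fkbp5 (1.1e-05), Tsc22d3 (1.3e-05), Prcp (1.5e-05) and Phlda3 and Ces2e (1.6e-05) did so too. Etnppl (1.9e-05), Fzd4 (2e-05), Cd83 (2.2e-05), Vegfc (2.6e-05), Clec14a (2.8e-05), Angpt2 (3.3e-05), Polk (3.5e-05), Alas2 (3.8e-05), Il1r1 (4.1e-05), Bst2 (4.4e-05), Sgk1 (4.7e-05), Prom1 (5e-05) and Ddc (5.6e-05) did as well. Sp100 (6.7e-05), Robo4 (6.9e-05), Dusp1 (7.9e-05), Tmem252 (8.2e-05), Prr18 (9.4e-05), Isg15 (9.8e-05), Slc38a5 and Nfkbia (1e-04), Itga2 (0.00011), Hbb-bt and Fgfbp1 (0.00013), Unc5b (0.00015), Oas1a (0.00016), Irgm2 (0.00022) and Dll4 (0.00024) did so too. T, Col15a1 and Gbp4 (0.00025), Ndrg1 (0.00027), Ly6a (0.00031), Cdkn1a (0.00032), Ifi44 (0.00036), Vwf (0.00038), Lao1 (0.00039), Spp1 (0.00041), Clca3a1 (0.00047), Rtp4 and Acta2 (0.00048), Abcg2 (0.00054), Usp18 and Gja4 (0.00071) and Gbp9 (0.00072) did as well. Zmat3 (0.00075), Mlkl (0.00076), Zfp36 (0.00079), Gbp3 (8e-04), Irf7 (0.00093), Nkd1 (0.00094), Serpinf1 (0.00099), Adm and Atoh8 (0.001), Eda2r (0.0012), Hba-a2 (0.0013), Lcn2 and Egr1 (0.0016), Notch4 (0.0018) and Rp1 (0.0019) did so too. Alox12 and Bnip3 (0.0022), Oasl2 (0.0026), Bbc3 (0.0032), Upk1a (0.0035), Fam196a (0.0036), Dcxr (0.0039), Hmox1 (0.0043), Hba-a1 (0.0045), Tnfrsf19 and Apobec3 (0.0047), Aen (0.0057), Ifit1 (0.0058), Alpl and Fn1 (0.006) and Gkn3 (0.0071) did as well. B2m (0.0072), Cd34 (0.0097), Lyz2 and Smad6 (0.01), Smad1 and Madcam1 (0.011), Sox17 and Ctnnb1 (0.012), Bmp4 (0.013), Tubb1 (0.019), Kdr (0.028), Cldn5 (0.031), Pvt1 (0.032), Oasl1 (0.033), Lef1 (0.039) and Cav1 (0.04) did so too. Prrg4 (0.045) and Tnfrsf10b (0.047) did as well.

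P9 differed in 4809 genes, against 94, 91 and 15 at the other stages. Pericyte markers fell at P9. Fewer mural cells predict falls. The 2497 here were not tested, and 727 rises of at least 2-fold cannot decide it. Gene length and GC content as the whole cause were argued against by the 4969 calls left after their trends were removed, 1.03 times the count, 4209 of them the same genes in the same direction. A single library was argued against by counts of 4199, 5100 and 4169 without KO library 1, 2 or 3, the lowest 0.87 of the full count. Cell mix and Sox17 loss stayed open and untested as causes.

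At P5 Eda2r, Phlda3 and Gdf15, targets of p53, were among the largest rises, and p53 pathway activity is a candidate explanation: 14 other targets had a median log2 fold change of 0.38 (100th percentile of random lists, whose 95th was 0.1), with Bbc3 (0.78), Polk (0.82), Tnfrsf10b (0.84) and Aen (0.76) called. The median was -0.01 at E15.5, 0.37 at P9 (percentile 99.6) and -0.04 in adults. Tnfrsf10b lost the call without each of the 6 libraries (adjusted p 0.071 to 0.22), and Gdf15 (0.075 to 0.11) and Bbc3 (0.052 to 0.18) without any but KO library 2. Cre recombinase activity and loss of Sox17 cannot be told apart, since 0 libraries were Cre-positive with intact Sox17.

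Rp1 rose in KO at every stage; it lies 81.7 kb downstream of Sox17 on the same strand, with 0 protein-coding genes between. Transcription running on from the recombined Sox17 locus is a candidate explanation: of 11 other tested genes within 1 Mb, 1 was called upward at any stage, Rgs20 at P9 (0.83, adjusted p 0.043), and the explanation allowed at most 1. Rgs20 lost the call without wt library 1 (0.15), wt library 3 (0.1) or KO library 1 (0.21). No value argued against it, reads between genes were not analysed here, and repression of Rp1 by Sox17 stayed open and untested.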

How the results depend on the processing

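The comparisons and their tests, the 20 gene and 13 marker lists, the named-gene rule and the alternatives were chosen before the data were examined. Exceptions, chosen after seeing the data, were the p53, glucocorticoid and platelet lists, the tests named so in this closing section, scaling to endothelial identity genes and leaving out both E15.5 libraries numbered 3. Of 656 results of named genes, 600 were called; 454 of these were called under every alternative but the fold threshold, and 146 were lost under 1 or more. The pseudocount alternative was not run, since it applies to normalized values, and the cause of the changes below was not tested except where stated.

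Without the low-count filter, calls were lost for Maml1 (adjusted p 0.088), Snai2 (0.075) and Rgs20 (0.077) at P9, Cdh5 (0.093) and Cgnl1 (0.052) averaged, and Ehd4 (0.12) and Tal1 (0.097) for wt P5 to P9. This called 212 genes at E15.5, 322 at P5, 69 in adults and 1579 for wt P5 to P9. DESeq2 called 148, 162 and 36 at E15.5, P5 and adult. Fits of the 6 compared libraries alone, which estimate the spread from fewer libraries, called 16, 205 and 40, and 2063 for wt P5 to P9. Without both E15.5 libraries numbered 3, 53 genes were called at E15.5. A fold threshold of log2 1 left, by construction, 52 genes at P5, 1425 at P9, 9 in adults, 118 averaged over stages, 1237 for the interaction, 61 in the overlap of stages, and 6346, 396, 5473 and 7207 for wt E15.5 to P5, P5 to P9, P9 to adult and E15.5 to adult. Scaling to endothelial identity genes called 2439 genes averaged over stages. With an estimated correlation 14 of the 50 list calls of KO contrasts and 5 of the 44 of wt contrasts passed. With a mean of at least 100 counts, the maturation correlation was 0.12 at P5 and 0.11 at P9.

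Without 1 library, the remaining libraries of a group are assumed to vary like the other groups, and fewer libraries lower the power. Counts ranged from 55 to 93 at E15.5, 36 to 82 at P5, 3650 to 5100 at P9, 4 to 14 in adults, 1172 to 1818 averaged, 1675 to 2578 for the interaction, 10567 to 11106 for wt E15.5 to P5, 305 to 630 for P5 to P9, 9494 to 9712 for P9 to adult, 11191 to 11631 for E15.5 to adult, and 46 to 53 and 42 to 45 for KO and wt lists. Counts moved by over 1.5 times at E15.5 without wt library 1 (55), KO library 1 (55) or KO library 2 (61). At P5 they did so without wt library 1 (36), wt library 3 (43), KO library 1 (38) or KO library 3 (44), and in adults without wt library 1 (6), 2 (4) or 3 (7) or KO library 1 (9) or 2 (8). For wt P5 to P9 they did so without P5 library 1 (546) or 3 (364) or P9 library 1 (439), 2 (305) or 3 (448). The dissociation list at E15.5 turned upward without wt library 3, and its adjusted p without 1 library ranged from 1.8e-05 to 0.83.

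Scaling to endothelial identity genes reversed 30 values of named genes in wt contrasts by construction, as it moved all genes by a common shift. From E15.5 to P5 the reversed values were Tnfrsf19 -0.15, Lrp5 -0.28, Ehd4 -0.26, Ehd2 -0.37, Sox7 -0.68, Sox18 -0.9, Notch4 -0.42, Notch1 -0.37, Pcna -0.51, Cdk1 -0.76, Mcm3 -0.73, Mcm2 -0.75, Bmpr2 -0.21, Nfkbia -0.51, Eno1 -0.79, Lef1 -0.76, Axin2 -1.45, Slc2a1 -0.91, Cdh5 -0.34 and Pecam1 -0.24. From P9 to adult they were Cdh5 0.06, Emp1 0, Pacsin2 0.34, Cldn5 0.14 and Pecam1 0.23, and from E15.5 to adult Lrp5 -0.14, Jag2 -0.16, Axin2 -0.62, Mfsd2a -0.76 and Cdh5 -0.6.

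A replicate block, by the number within each stage, gave 88, 119, 4945 and 16 genes at E15.5, P5, P9 and adult, 1630 averaged, 2385 for the interaction, 11444, 961, 10544 and 11918 for wt, and 51 and 45 lists. It ended the calls of Treml1 (adjusted p 0.087), Vwf (0.088) and T (0.11) at E15.5, of Fam196a (0.064), Upk1a (0.064), Notch4 (0.14) and Mecom (0.16) in adults, of Cdh5 (0.077) and Cgnl1 (0.066) averaged, and of Ehd4 (0.053) for wt P5 to P9. Libraries of wt correlated best with the KO library of their own number for 3 numbers of 3 at E15.5 (0.06, 0.37 and 0.49), and for 2, 1 and 2 at P5, P9 and adult.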

Other observations

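The genes named in this part and the tests of platelets and of Esr1 were chosen only after the results were seen. Outside the fixed lists, B2m, the light chain of MHC class I, rose from 67.6 ± 14 to 120 ± 3.56 CPM at E15.5 (SD, n = 3) and from 221 ± 43.8 to 374 ± 25.3 at P5. Gbp9 (1.18 and 0.73) and Irgm2 (1.11 and 0.77), interferon-induced GTPases, Sp100 of nuclear bodies (2.01 and 1.17) and Mlkl, the effector of necroptosis (1.37 and 0.85), rose at both stages. At P9 values were -0.15 for B2m and -0.04 for Sp100. At E15.5, B2m lost the call without wt library 1 (0.18), KO library 1 (0.071), KO library 2 (0.057) or KO library 3 (0.063). No call remained for B2m, Gbp9, Irgm2, Sp100 and Mlkl in a fit of the 6 compared libraries alone (adjusted p 0.13 to 0.29), nor for B2m (0.078) without both E15.5 libraries numbered 3. At P5, B2m (adjusted p 0.087 to 0.27), Gbp9 (0.069 to 0.22) and Irgm2 (0.12 to 0.3) lost their calls without any library but wt library 2, and Mlkl without wt library 1 (0.087) or 2 (0.058) or KO library 3 (0.06). Calls ended for Irgm2 (0.078) with scaling to endothelial identity genes.

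The cell cycle inhibitor Cdkn1a, a target of p53, rose from 162 ± 15.7 to 372 ± 79.4 CPM at P5 and from 206 ± 5.64 to 659 ± 124 at P9 (SD, n = 3; 1.67, adjusted p 3.9e-07). Zmat3 rose by 1.08 and 0.7, and Trp53inp1 by 1.47 and 2.55. Mki67, a marker of cycling cells, had a value of 0.26 at P5 and fell by -1.8 at P9 (adjusted p 1.3e-08).

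A glucocorticoid-type stress response is a candidate explanation for the P9 rises in Hif3a and Zbtb16. The 16 other glucocorticoid-induced genes all rose at P9, by a median log2 fold change of 1.76 (100th percentile of random lists, whose 95th was 0.21), among them Fkbp5 (35.2 ± 1.08 to 121 ± 35.3 CPM), Tsc22d3 (1.75), Sgk1 (1.55) and Ddit4 (2.29). Their median was -0.05 at E15.5, 0.25 at P5 (also the 100th percentile, 95th 0.09), where none was called, and 0.05 in adults. Hormone levels and handling of the animals were not measured here.

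Fewer platelets or megakaryocytes in the E15.5 KO fraction may underlie the falls of Tubb1 and Treml1. Of 10 other platelet genes 9 were tested, with a median of -0.59 (percentile 0.03 of random lists), although none was called alone. The median was 0.26 (percentile 97.1) at P5, 0.32 (84.4) at P9 and 0.33 (98.1) in adults. Treml1 lost the call without wt library 1 (0.13), wt library 2 (0.2), wt library 3 (0.091), KO library 1 (0.24) or KO library 2 (0.32).

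Esr1 lay above the highest wt library, at 1.13 CPM, in 12 of 12 KO libraries, at 7.49 to 29.8 CPM. Transcripts of the CreERT2 transgene, which holds part of the human estrogen receptor gene, and transcripts of Esr1 itself cannot be told apart, since the counts are per gene and the driver was present in KO libraries only.

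Xist, which is transcribed from an inactive X chromosome, was at 0.714 CPM or lower in E15.5 wt library 2 and KO library 2, P5 wt libraries 1 and 2 and KO library 1, and P9 KO library 3. It was at 534 to 1920 CPM in the other 18 libraries.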
